A study of Mus musculus with 8 samples.

How the data were processed

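Single-cell RNA sequencing was carried out on CD45+ cells that the submitters sorted magnetically from normal brain and from the tumours of glioma-bearing mice. GEO's labels list 8 samples, 4 controls and 4 gliomas. They name droplet kits of either of 2 chemistry versions and an Illumina HiSeq X. The submitters' processing notes name Cell Ranger 3.0.2, STAR (no version), Seurat 3 and the builds GRCh38 and mm10; every gene identifier was a mouse Ensembl identifier.

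The authors deposited raw counts: each value is the number of unique molecular identifiers (UMIs) of a gene at a droplet barcode, without normalization. There was 1 matrix per group, with 31053 genes and all 6794880 barcodes of the kit's list, so no filter for cells had been applied. Each matrix carried 1 barcode suffix, and no file or label assigned barcodes to animals or samples. Each group was therefore treated as 1 pooled library. The control library held 124023146 UMIs and the glioma library 159689787.

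Cells were called in each library by a Monte Carlo test (2000 simulations) of each barcode's profile against the free RNA of its library, in the manner of EmptyDrops. The free RNA profile came from the barcodes ranked 45000 to 90000 by UMIs; barcodes with at least 300 UMIs in the other library stayed in for cell calling and were left out wherever free RNA was subtracted or its level given. Barcodes of at least 500 UMIs with a false discovery rate of at most 0.01 were kept, as were those above an order-of-magnitude limit (3647.2 UMIs in the control and 5866.9 in the glioma library). Barcodes with fewer than 300 genes or more than 10% mitochondrial UMIs were removed. Scrublet's automatic threshold marked 0% of cells as doublets, so the cells with the highest scores were removed at 0.8% per 1000 cells, a rule fixed for that case. In the control library 16951 barcodes were called, 976 and 2510 failed the gene and mitochondrial limits, 1597 were removed as doublets, and 11868 cells with a median of 6665.5 UMIs and 2235 genes remained. In the glioma library 11543 were called, 74 and 539 failed the limits, 999 were removed as doublets, and 9931 cells with a median of 10838 UMIs and 2627 genes remained. On simulated droplets, 0% of the control and 0.5% of the glioma droplets made of free RNA alone were called as cells. Of simulated shallow droplets that mixed free RNA with RNA of real cells, 25.75% in control and 19.5% in glioma were called. The test therefore missed most such droplets.

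Cells of both libraries were clustered together without integration, since library and group are the same thing here. UMIs were scaled to 10000 per cell and log-transformed; 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 were used, which gave 26 clusters. Clusters were named by 20 marker lists, for microglia, monocytes or macrophages, border-associated macrophages, dendritic cells, plasmacytoid dendritic cells, neutrophils, T cells, NK cells, B cells, plasma cells, mast cells or basophils, astrocytes, oligodendrocytes, oligodendrocyte precursors or tumour cells, endothelium, pericytes or smooth muscle, fibroblasts, neurons, ependymal or choroid cells and erythroid cells. A marker counted when it was at least 2-fold over the median cluster or over all other cells and was seen in at least 0.05 of the cluster's cells. A name needed at least 4 counted markers, a lead of at least 3 over the next list, and no more genes of another list among the cluster's 10 leading genes. Clusters between the 2 macrophage lists were called macrophage-like, and clusters of shallow cells without a marker of their own among the leading genes stayed unnamed. The marker lists were fixed before the data were examined, as were the gene lists, the comparisons, the rule for named genes and the alternatives, except where stated. The naming rule was set after the clusters had been seen and was revised several times, among others because a cluster of 69 glioma microglia-like cells was named under some settings and not under others. It named 20 of the 26 clusters.

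UMIs were summed over each class and expressed as CPM, a scale on which the total of every class is the same. Ratios are log2 of the CPM ratio with 0.5 UMIs added to each sum. For a gene at 0 UMIs in a sum, the fold was computed against 3 UMIs of that sum and is a lower bound. Because each group is 1 pooled library, no test was run on expression or class shares. Intervals are 95% and exact (Clopper-Pearson for shares, Poisson for sums, conditional binomial for ratios), and they cover counting error only, not differences between animals. A gene list was summarised by the median log2 ratio of its members with at least 20 UMIs over both sums, and placed as a percentile among 10000 random lists of the same size and expression. On simulated sums of the size of the microglia comparison, 94 to 98% of intervals held the true ratio.

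Leiden resolution 1 over both libraries gave only 3 glioma microglia-like and 41 control T cell-like cells, under the minimum of 50. After this had been seen, both comparisons with glioma microglia-like cells were taken from clusterings of each library by itself, and the T cell comparison from Leiden resolution 0.5; both were among the listed alternatives. The 17 gene lists were homeostatic microglia, disease-associated microglia, MHC class I and cross-presentation, MHC class II, type I interferon response, interferon gamma response, immunosuppressive mediators, cholesterol biosynthesis, cholesterol efflux and LXR targets, glycolysis and hypoxia, immediate early and dissociation response, inflammatory cytokines and chemokines, proliferation, lysosome and phagocytosis, T cell activation and exhaustion, naive and circulating T cell, and the Nr4a family.

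Named genes were the 12 with the largest and the 12 with the smallest ratio among genes with at least 50 CPM in the higher sum and 100 UMIs over both, the Nr4a family, Sqle, and 2 to 4 members of each list with the largest absolute ratios at 20 CPM or more in the higher sum. Mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin, Y-linked and predicted genes and Xist were left out. The share of cells with an Nr4a2 UMI was also taken after cells were thinned to 2000 UMIs, with shallower cells left out. Gene coordinates are from GENCODE vM21 on GRCm38/mm10.

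Alternatives covered cell calling (at least 1000 UMIs and 500 genes, or at least 2000 UMIs), mitochondrial limits of 5% and 20%, doublets kept, Leiden resolutions of 0.5 and 2, each library clustered by itself, median-of-ratios scaling, the mean of per-cell CPM, subtraction of free RNA, minimums of 100 UMIs or none, and lists without their cell type markers. After the subtraction, a gene with at most 3 UMIs in both sums was given no ratio. The most RNA of other cells that the glioma microglia-like droplets could hold was found by linear programming over the profiles of the glioma clusters, with each gene of at least 50 CPM in a cluster held under its upper Poisson limit (error rate 0.05 over all genes). The free RNA share of each class was set by markers taken as foreign to it. These were microglia markers for T cells, neutrophils and endothelium, and T cell markers for all other classes. The choice was revised 2 times after implausible values had been seen. Cells of the T cell comparison with more than 10% microglial RNA left out, pooled T and NK clusters, and a comparison of neutrophils were added after the data had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.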

Results

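The data describe CD45+ cells, mostly leukocytes and microglia, from normal mouse brain and from mouse glioma, profiled by droplet single-cell RNA sequencing. The labels list 4 control and 4 glioma samples, but the counts form 1 pooled library per group. The control library held 124023146 UMIs, with 11868 called cells at a median of 6665.5 UMIs. The glioma library held 159689787 UMIs, with 9931 cells at a median of 10838 UMIs. No paired analysis was possible because the cells carry no map to animals, and there are no replicates against which a difference could be tested. All intervals below are exact 95% intervals for counting error.

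The first comparison asked which CD45+ cells were found in tumour and in normal brain. Microglia-like cells, which carried P2ry12 and Tmem119, made up 78.8% of control cells (78.0 to 79.5%) and 0.03% of glioma cells (0.006 to 0.088%, 3 of 9931 cells; 69 cells or 0.695% where each library was clustered by itself). The 3 macrophage classes together made up 3.18% of control cells (2.87 to 3.51%) and 71.2% of glioma cells (70.3 to 72.1%). T cell-like cells were 0.345% of control and 10.99% of glioma cells, dendritic cell-like cells 0.042% and 6.57%, and neutrophil-like cells 0.674% and 5.14%. Endothelial-like cells were 1.08% of control cells, and 0 of 9931 glioma cells, with an upper limit of 0.037%.

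**Figure D1:**
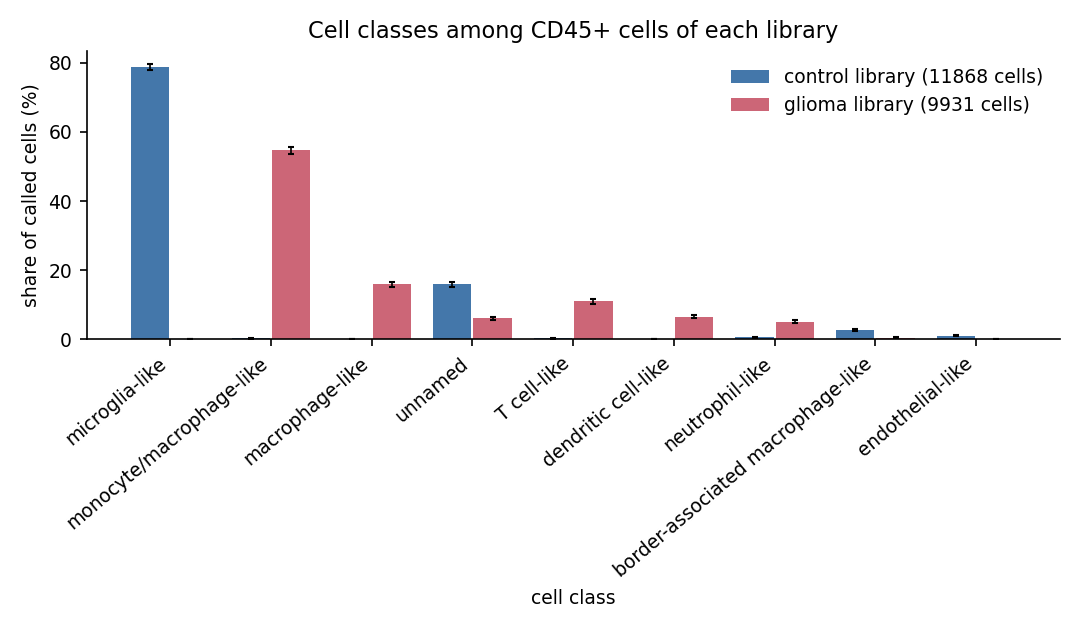
Share of called cells (percent, vertical axis) in each cell class (horizontal axis) for the control library (blue, 11868 cells) and the glioma library (red, 9931 cells), with exact 95% intervals for counting error. Microglia-like cells were 78.8% of control and 0.03% of glioma cells, and monocyte/macrophage-like cells were 0.362% and 54.6%.

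Glioma monocyte/macrophage-like cells, 54.6% of the library, fell into 4 clusters. The largest, with 2579 cells, was led by Cxcl9, a chemokine induced by interferon gamma, with the monocyte receptor Ccr2 and the MHC class II activator Ciita. A cluster of 1829 cells was led by Inhba, Thbs1, Nrg1, Vegfa and Il1rn. A cluster of 809 cells was led by Chil3, Arg1, Vcan and Spp1, and a cluster of 209 cells by the type I interferon-induced genes Rsad2, Ifit1 and Ifit2. Macrophage-like cells, 16.0% of the library, comprised 1190 cells led by Mmp13, Vcam1 and Mrc1 and 399 cells led by the cycle genes Top2a, Pclaf and Mki67. Glioma T cell-like clusters were led by Ccl1, Tnfrsf4, Ifng and Gzmf (652 cells), by Gzmb, Nkg7 and Cd8a (352 cells) and by Trdc and Il17a (87 cells). Dendritic cell-like clusters were led by Plet1, Ccl17 and Itgae (570 cells) and by Ccl22 and Ccr7 (82 cells).

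Control microglia-like cells fell into 6 clusters, 5 of them described here. Clusters of 1485 and 1840 cells were led by the homeostatic genes Tmem119 and Sall1 in turn. A cluster of 1928 cells was led by Gpr84, Il1a and Tnf, and 1501 cells were led by Gdf15, Ccl4 and the immediate early gene Egr1. A cluster of 110 cells was led by interferon-induced genes (Ifit3, Ifit2, Usp18). Border-associated macrophage-like cells, with Cbr2, Lyve1 and Cd163, were 2.65% of control cells.

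Unnamed clusters held 15.9% of control and 6.10% of glioma cells; an unnamed cluster of 1205 control cells had all 12 microglia markers raised in its sum but was led by Atf3, Klf2 and haemoglobin genes. In the joint clustering, 46 of the 69 cells lay among the border-associated macrophage-like cells, which were therefore not compared between libraries. Clustering by itself also named NK cell-like (142), B cell-like (39) and plasmacytoid dendritic cell-like (28) clusters in the glioma library. There, border-associated macrophage-like cells were 10.6% of glioma cells (1051) and macrophage-like cells 4.46%, against 0.544% and 16.0% in the joint clustering. No cluster was named for plasma cells, mast cells or basophils, astrocytes, oligodendrocytes, oligodendrocyte precursors or tumour cells, pericytes or smooth muscle, fibroblasts, neurons, ependymal or choroid cells or erythroid cells.

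The study's title concerns Nr4a2, an orphan nuclear receptor of the NR4A family (ENSMUSG00000026826, chromosome 2, 57106830 to 57124003, minus strand). Of the classes with at least 50 cells, control microglia-like cells had the lowest Nr4a2, at 4.12 CPM (3.64 to 4.64; 268 UMIs in 9347 cells), and glioma monocyte/macrophage-like cells had 110 CPM (107 to 112). In the clustering of both libraries, other glioma classes lay between, with 94.1 CPM in dendritic cell-like, 72.4 CPM in macrophage-like, 70.9 CPM in T cell-like and 65.6 CPM in neutrophil-like cells. Clustered by itself, the glioma library had 127 CPM (106 to 150) in 142 NK cell-like and 121 CPM in monocyte/macrophage-like cells. The estimate of free RNA took T cell markers as foreign to the NK cell-like cells and reached its maximum of 100%. In the joint clustering, a cluster counted 11 NK and 11 T cell markers, so these may not be foreign. The 100% is therefore no measure of free RNA. Even at that maximum, free RNA could bring no more than 65.5 CPM there. The estimate for the monocyte/macrophage-like cells was 2.62 CPM. Nr4a2 was not confined to the tumour, since control endothelial-like cells had 196 CPM and control border-associated macrophage-like cells 90.3 CPM. Among the monocyte/macrophage-like clusters, the one led by Inhba, Thbs1 and Vegfa had 157 CPM (152 to 163), against 82.2 CPM in the Cxcl9 cluster, 88.2 CPM in the Chil3 and Arg1 cluster and 93.3 CPM in the interferon cluster.

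**Figure D2:**
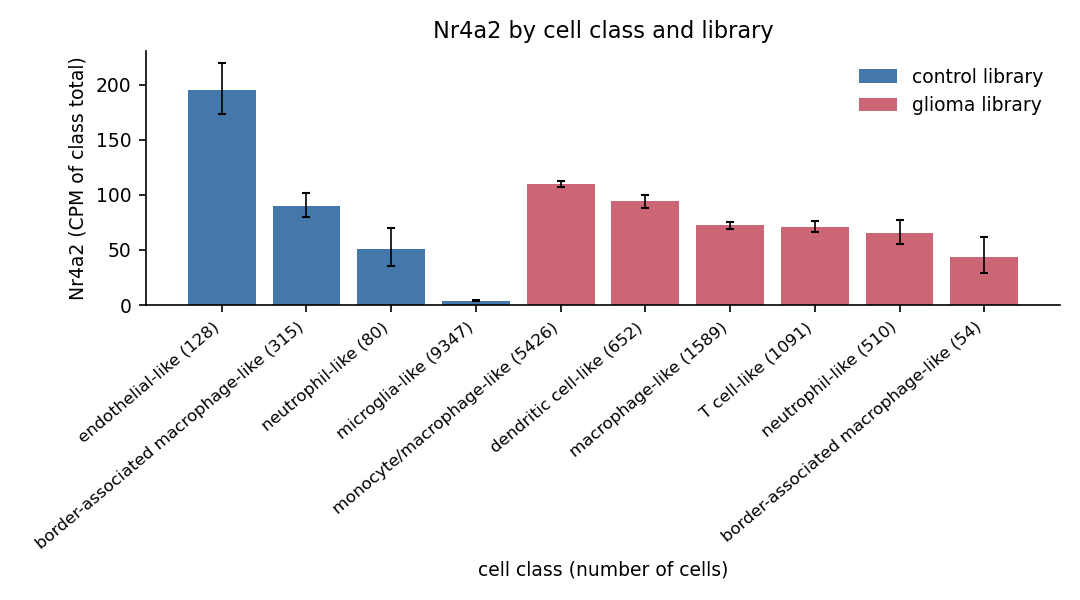
Nr4a2 level (CPM of the class total, vertical axis) in each class with at least 50 cells (horizontal axis, number of cells in parentheses) of the control library (blue) and the glioma library (red), with exact 95% intervals for counting error. The level was 4.12 CPM in control microglia-like cells and 110 CPM in glioma monocyte/macrophage-like cells.

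Nr4a1 (chromosome 15, 101254269 to 101274795, plus strand) had 240 CPM in control microglia-like and 113 CPM in glioma monocyte/macrophage-like cells. Within control microglia-like cells it was highest in the clusters led by Gpr84 (416 CPM) and Gdf15 (552 CPM); the Sall1 cluster had 31.2 CPM, below the 75.1 to 140 CPM of the glioma monocyte/macrophage-like clusters. Nr4a3 (chromosome 4, 48045153 to 48086447, plus strand) had 15.6 and 66.0 CPM. Sqle, which encodes squalene epoxidase of cholesterol synthesis (chromosome 15, 59315077 to 59331192, plus strand), had 1.43 CPM in control microglia-like, 17.5 CPM in glioma monocyte/macrophage-like and 18.5 CPM in glioma dendritic cell-like cells. With cells thinned to 2000 UMIs, 17.1% of 5133 glioma monocyte/macrophage-like cells (16.1 to 18.2%) had an Nr4a2 UMI. The share was 0.69% of 8681 control microglia-like cells (0.53 to 0.89%). Shallower cells were left out, 293 and 666 in turn, and the median depths before thinning were 10191.5 and 6899 UMIs. No class was fixed beforehand as lacking Nr4a2, and the free RNA of the glioma library itself held Nr4a2 at 65.5 CPM, the level of the glioma neutrophil-like cells, against 11.4 CPM in the control library.

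The second comparison asked how microglia in the tumour differed from those of normal brain, from 69 glioma microglia-like cells (924372 UMIs) and 9438 control microglia-like cells (65108379 UMIs). Glioma microglia-like cells had a lower median of the homeostatic list and higher medians of the disease-associated, MHC and interferon response lists. Homeostatic genes had a median log2 ratio of -2.59, with 16 of 18 members at least 2-fold lower; P2ry12, a purinergic receptor of resting microglia, had 134 CPM in glioma and 2237 CPM in control (log2 ratio -4.05, -4.33 to -3.81), and Siglech (-4.59), Slc2a5 (-4.45) and Gpr34 (-3.66) were lower too. Disease-associated microglia genes had a median of 1.54, with 11 of 19 at least 2-fold higher and 1 lower. Apoe, the lipid carrier, led this list with 45300 CPM in glioma and 867 CPM in control (5.71, 5.69 to 5.73), followed by Lgals3 (5.02), Fabp5 (4.87) and Spp1 (3.87).

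Antigen presentation and interferon lists had higher medians in the glioma microglia-like cells. MHC class II had a median of 2.54 (7 of 10 at least 2-fold higher, 1 lower), with H2-Aa at 6.73, H2-Eb1 at 6.72, H2-Ab1 at 6.03 and Cd74 at 5.19. MHC class I and cross-presentation had a median of 0.68 (9 of 19 higher, 0 lower), led by Cybb (5.83), the peptide transporter Tap1 (2.12) and H2-D1 (2.12). The type I interferon response had a median of 2.0 (17 of 18 higher), with Ifi204 at 3.77 and Irf7 at 3.57. The interferon gamma response had 2.21 (11 of 14 higher), with Gbp2 at 4.25 and Cxcl9, the largest ratio of the comparison, at 10.82 (10.18 to 11.62; 513 and 0.28 CPM). Proliferation genes had 1.43 (13 of 20 higher), with Birc5 at 7.08 and Mki67 at 4.88, and glycolysis and hypoxia genes 0.80 (6 of 17 higher, 2 lower), with Pfkp at 4.19 and Vegfa at 4.03.

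Immediate early and dissociation genes had a median of -1.40 (12 of 21 at least 2-fold lower, 0 higher), with Jun at -2.63, Atf3 at -2.09 and Hspa1b at -1.88. Inflammatory cytokines and chemokines had -0.76 and went both ways (6 of 17 higher, 8 lower), with Ccl5 at 4.28, Ccl2 at 2.82, Tnf at -2.44 and the NF-kB inhibitor Nfkbia at -2.68. Immunosuppressive mediators had 1.54 (7 of 13 higher, 1 lower), with Gpnmb at 3.79, Il1rn at 3.58 and Mrc1 at 2.76. Nr4a2 had 24.9 CPM (15.8 to 37.3) in glioma and 4.39 CPM (3.90 to 4.93) in control, a log2 ratio of 2.53 (1.82 to 3.12) from 23 glioma UMIs. Nr4a3 (2.11) was higher and Nr4a1 (-0.54, -0.78 to -0.33) lower, and the Nr4a family had a median of 2.11. Sqle had 2 glioma UMIs and a ratio of 0.90 (-2.48 to 2.48).

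Cholesterol biosynthesis (0.08), cholesterol efflux and LXR targets (0.22), lysosome and phagocytosis (0.28), T cell activation (-0.33) and naive T cell genes (-0.82) lay within the central 95% of random lists, although members such as Pmvk (2.78), Msr1 (7.19), Cd36 (6.52), Mertk (-1.18) and Lag3 (-1.10) were far from 0. Fn1 (8.39), the integrin Itgal (7.65), the complement gene C4b (7.59), Pla2g7 (7.50), Apoc1 (7.38), Cp (6.98), Iigp1 (6.86), Aoah (6.86) and Ifitm1 (6.76) were among the largest ratios. Fn1 and Itgal were also monocyte/macrophage markers, and Cxcl9 led the largest glioma monocyte/macrophage-like cluster. How much macrophage RNA in the same droplets could bring to these ratios was not computed. Among the smallest, Serpinf1 was at least 26.9-fold lower, Gp9 at least 20.3-fold, Csmd3 at least 19.0-fold, Klhdc8b at least 17.7-fold and Upk1b at least 17.2-fold, and Ttr, a choroid plexus transcript, was at least 81.0-fold lower (at most 3 UMIs remained in either sum once free RNA was subtracted). If macrophage RNA had the summed profiles of the glioma macrophage clusters, their genes allowed at most 10.8% of it in these droplets. Such RNA could bring at most 11.4 of the 20.5 CPM by which Nr4a2 exceeded control. For 6 MHC class II genes, it could bring at most a median of 48.9% of the excess. The median of the immunosuppressive list was -0.09 without its cell type markers or with at least 100 UMIs per gene. Without a minimum it was 2.53. The medians of MHC class II and proliferation were 1.18 and 0.84 with at least 100 UMIs. That of cholesterol efflux was -0.13 as a mean over cells, that of T cell activation 2.44 without a minimum, and that of the homeostatic list -1.73 without markers.

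**Figure D3:**
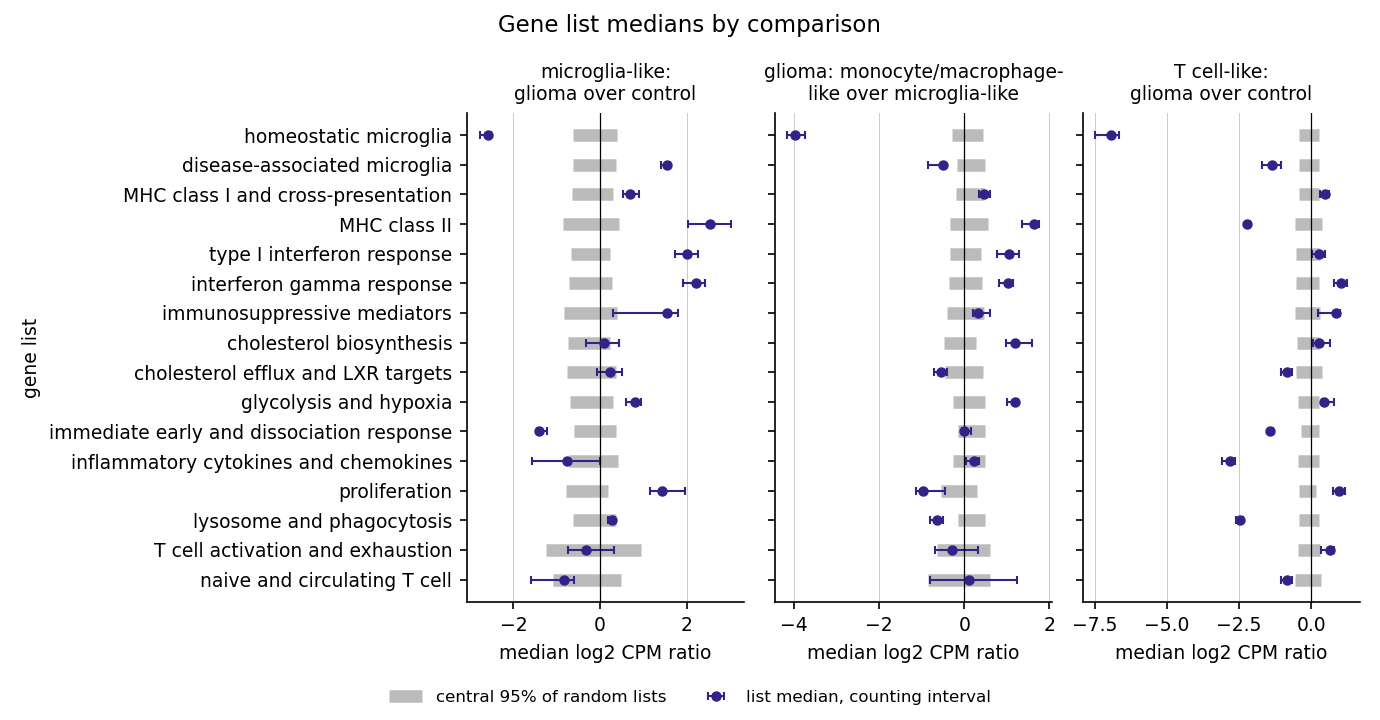
Median log2 CPM ratio (horizontal axes) of each gene list (vertical axis) in the microglia-like, macrophage and T cell-like comparisons, with intervals for counting error (dots and bars), over the central 95% of 10000 random lists of matched expression (grey). The homeostatic list stood at -2.59, -3.99 and -6.94 and the MHC class II list at 2.54, 1.64 and -2.22; the T cell MHC class II value was 0.14 with doublets kept.

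The third comparison set 4343 monocyte/macrophage-like cells (48097647 UMIs) against the 69 microglia-like cells within the glioma library, so that both sides share a library. Left out were, among others, 1051 border-associated macrophage-like cells, 443 cycling macrophage-like cells and 916 unnamed cells nearest to the monocyte/macrophage list. The differences below are therefore those of the named class, not of all glioma macrophages. In monocyte/macrophage-like cells the medians of the MHC class II, interferon, glycolysis and cholesterol synthesis lists were higher, and those of the homeostatic, disease-associated, lysosome and cholesterol efflux lists lower, than in microglia-like cells. Nr4a2 was higher in the monocyte/macrophage-like cells, at 121 CPM (118 to 125) against 24.9 CPM (log2 ratio 2.26, 1.70 to 2.95). Nr4a1 was lower (-0.72), and Nr4a3 did not differ beyond counting error (0.20, -0.14 to 0.59). The family's median was 0.20. MHC class II had a median of 1.64 (7 of 10 at least 2-fold higher, 1 lower), with Ciita at 2.16, H2-Eb1 at 2.02 and H2-Aa at 5303 against 1328 CPM. MHC class I and cross-presentation had 0.47 (2 of 19 higher, 0 lower), with Psme2 at 1.06 and H2-D1 at -0.68.

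Type I interferon genes had a median of 1.04 (9 of 18 higher), with Rsad2 at 2.46 and Ifitm3 at 1.79, and interferon gamma genes 1.02 (7 of 14), with Gbp4 at 2.20. Cholesterol biosynthesis had 1.19 (14 of 22 higher, 1 lower), with Cyp51 at 1.83 and the regulator Srebf2 at 1.66, and Sqle had 15.9 CPM against 2.16 CPM (2.56, 1.02 to 5.93, 2 microglia UMIs). Cholesterol efflux and LXR targets had -0.56 (5 of 12 lower, 2 higher), with Apoe at -2.58, Mylip at -1.78 and Npc1 at -1.18. Glycolysis and hypoxia genes had 1.19 (10 of 17 higher, 2 lower), led by Ndrg1 (3.23), Pfkp (2.66), Ero1l (2.32) and Vegfa (2.06). Immunosuppressive mediators had 0.33 (7 of 15 higher, 2 lower), with Arg1 at 547 against 11.9 CPM (5.46, 4.68 to 6.53), Il1rn at 2.58 and Cd274, which encodes PD-L1, at 1.22.

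Lysosome and phagocytosis genes had -0.64 (7 of 18 lower, 0 higher), with Mertk at -1.81 and Grn at -1.78. Disease-associated microglia genes had -0.49 (8 of 19 lower, 4 higher; -1.02 with 20% mitochondrial UMIs allowed, -0.93 with at least 2000 UMIs and -0.86 at resolution 2), with Cst7 at -6.84, Ctsd at -3.83 and Trem2 at -3.20. Proliferation genes had -0.98 (11 of 22 lower, 1 higher), with Birc5 at -2.79. The 443 macrophage-like cells led by Top2a and Mki67 lay outside the class, so this median does not describe cycling in all glioma macrophages. Likewise, the 916 unnamed cells led by Ccl12 lay outside it, which bears on the Ccl12 ratio below. Homeostatic genes had -3.99 (16 of 17 lower), many of them markers that name the class (-1.77 without these), with Sparc at -9.19, Crybb1 at -8.22, Fcrls at -6.18 and Olfml3 at -5.77. Immediate early (-0.01), inflammatory (0.22), T cell activation (-0.30) and naive T cell (0.11) lists had medians within the central 95% of random lists, which turned to 0.18 for immediate early genes with 20% mitochondrial UMIs allowed and, without a minimum, to -0.22 for inflammatory and -1.0 for naive T cell genes; Ccl12 (-4.27), Ccl4 (-2.59), Ccl9 (2.65) and Nos2 (4.10, 2.57 to 7.47, 2 microglia UMIs) were members far from 0. Among the largest ratios, Ly6c2, a marker of inflammatory monocytes, was at least 64.2-fold higher, Hp at least 32.1-fold and Upp1 at least 29.6-fold, Plac8 stood at 6.34, and Chil3 had 8.35 (6.82 to 11.72, 2 microglia UMIs). The direction of the Nr4a family median turned with doublets kept (-0.06) and at resolution 2 (-0.09), but that of Nr4a2 itself did not under any of 9 alternatives.

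The fourth comparison addressed T cells, on which immunosuppression would act, from 1597 glioma T cell-like cells (14953823 UMIs) and 132 control T cell-like cells (1196002 UMIs), clusters that also held NK markers. Glioma T cell-like cells had higher medians of the proliferation, activation and interferon gamma lists, and lower medians of the naive and immediate early lists. The make-up of the class differed: at resolution 1, 90 control and 424 glioma cells lay in an unnamed cluster of T and NK markers, and 41 and 1091 in T cell-like clusters, so the differences below include composition. T cell activation and exhaustion genes had a median of 0.63 (6 of 16 at least 2-fold higher, 2 lower), with the costimulatory receptor Tnfrsf9 at 328 against 40.1 CPM (3.02, 2.62 to 3.47), and the inhibitory receptors Ctla4 at 2.91 and Pdcd1 (PD-1) at 2.34, while the chemokine Ccl5 was lower (-1.47). Naive and circulating T cell genes had -0.86 (4 of 10 lower, 0 higher), with Igfbp4 at -2.90, Klf2 at -2.74, Dapl1 at -1.94 and Lef1 at -1.38. The granzymes Gzmf, Gzmd and Gzme were at least 106-fold, 73.0-fold and 60.6-fold higher, the enkephalin precursor Penk at least 61.9-fold and Tff1 at least 34.2-fold, and Tnfrsf4 (OX40) stood at 4.88, Ifitm1 at 4.82 and Lars2 at 5.70.

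Nr4a2 was lower in glioma T cell-like cells, at 77.2 against 202 CPM (-1.39, -1.59 to -1.18), and also within the T and NK cluster (87.5 against 185 CPM), as was Nr4a1 (-2.24), while Nr4a3 had 0.27 (0.01 to 0.55); the family's median was -1.39. Immediate early genes had a median of -1.42 (17 of 21 lower, 0 higher), with Fosb at -3.97 and Fos at -3.31. Within the T and NK cluster, glioma cells had Fos at 39.3 against 426 CPM. Their immediate early genes had a median of 165 against 426 CPM. The lower Nr4a2 thus went with a lower immediate early and dissociation signal, and the 2 were not separated. Proliferation genes had 0.96 (11 of 22 higher, 0 lower; 0.29 as a mean over cells and 0.36 without control cells above 10% microglial RNA), with Mki67 at 1.95 and Pclaf at 1.73. Interferon gamma genes had 1.04 (7 of 14 higher), with Gbp5 at 2.14, type I interferon genes 0.27, and MHC class I and cross-presentation 0.47 with Psmb9 at 1.37. Immunosuppressive mediators had 0.86 (6 of 15 higher, 4 lower), with Pdcd1lg2 at 2.35 and Vsir at -2.77. Glycolysis and hypoxia genes had 0.45 with Mif at 1.78, and cholesterol biosynthesis 0.26 with Sqle at 1.65 (0.43 to 3.71).

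Lists of microglial and myeloid genes had lower medians in the glioma T cell-like cells, but not all of them did with doublets kept. Homeostatic microglia genes had -6.94 (18 of 18 lower), led by Siglech, Fcrls and Olfml3, inflammatory genes -2.83 with Il1a at -5.56, lysosome and phagocytosis -2.48 with Mertk at -5.42, MHC class II -2.22 with Cd74 at -2.50, disease-associated genes -1.36 with Trem2 at -6.08, and cholesterol efflux -0.83 with Apoe at -2.29. With doublets kept, MHC class II had 0.14, disease-associated genes 0.29, Apoe 0.29, Mrc1 0.90 and Cybb 0.59, and the inflammatory (-1.57), lysosome (-1.18) and cholesterol efflux (-0.33) medians lay nearer to 0. Control T cell-like cells carried a median of 7.27% microglial RNA and 41.7% of them more than 10%, against a median of 0% in glioma. Over 5798 measured genes, the median log2 ratio was -0.19 in this comparison, and the list values above stand against it. With the control cells above 10% microglial RNA left out (77 remained), the homeostatic list had -4.35, lysosome -1.34, disease-associated -0.77, naive -1.30 and the immunosuppressive list 0.13; subtracting free RNA turned the type I interferon (-0.67; -0.09 with at least 1000 UMIs and 500 genes per cell) and cholesterol biosynthesis (-0.10) medians and left interferon gamma at 0.11, and the activation median was 0.12 as a mean over cells.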

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

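Every test of shared barcodes in this part was chosen after the result had been seen.

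Each library held a signal at barcodes that were cells of the other library only. The control library had a mean of 40.06 UMIs at 9846 such barcodes, against 1.998 at other barcodes under 300 UMIs, and the glioma library 20.72 UMIs at 11826, against 1.341. These barcodes entered no comparison as cells. Barcodes with at least 300 UMIs in the other library made up 20.2% of the control and 21.9% of the glioma barcodes of the free RNA profile used to call cells, and were left out of the profile used elsewhere. Molecules of the other library counted there are a candidate explanation: UMIs followed the other library's depth at the same barcode (Spearman 0.938 in the control and 0.858 in the glioma library), and T cell markers made up 0.531% of control-library UMIs at glioma T cell-like barcodes against 0.002% at monocyte/macrophage-like barcodes. Free RNA or barcode errors of the same library are argued against, since the profile was closer to cells of the other library than to its own by 0.283 (control) and 0.253 (glioma) in Spearman correlation. The signal equalled 0.3% and 0.285% of the other library's UMIs there, far below the 500 UMIs a cell needed; how molecules moved between libraries was not tested, and no biological explanation was tested.

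An unnamed cluster held 116 glioma cells and 0 control cells, 1.17% of glioma cells (0.97 to 1.40%). It was led by Rhox5, Krt8 and Krt18, with a median of 36168.5 UMIs and 4870 genes. Rhox5, a homeobox gene, had 935 CPM against 1.2 CPM in other glioma cells, the keratin Krt8 522 against 0.7 CPM, and the collagen chaperone Serpinh1 644 against 0.8 CPM. Nes had 70.1 against 0.2 CPM, Egfr 14.5 against 0.1 CPM and Col1a1 72.4 against 0.2 CPM, whereas Ptprc, which encodes CD45, had 10.5 CPM (7.8 to 13.9) against 371 CPM and the myeloid gene Lyz2 126 against 4343 CPM. Nr4a2 had 54.1 CPM against 93.2 CPM. Only 16.4% of these cells had a Ptprc UMI, so cells with little or no CD45 transcript were present despite the CD45 sort. Among markers with at least 20 UMIs, 3 of 4 of oligodendrocyte precursors or tumour cells were at least 2-fold over other glioma cells. So were 3 of 3 of fibroblasts and 3 of 3 of pericytes or smooth muscle. These lists do not tell a tumour from a stromal origin, and no cell type was assigned.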

How the results depend on the processing

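The T cell alternatives without cells above 10% microglial RNA or with pooled clusters, and the whole neutrophil comparison, were chosen after the data had been seen, as was the naming rule, which all settings share. No paired analysis was possible because the cells carry no map to animals. Over all alternatives 3507 values stayed within their counting interval, 772 moved beyond it and 20 were labelled reversed. The 20 are not all changes of sign, since some list medians that changed sign were counted as moved. Examples are type I interferon in T cells (0.27 to -0.671 with free RNA subtracted) and naive genes in macrophages (0.113 to -1.002 without a minimum). None of the 15 main results was labelled reversed, but the class shares and Nr4a2 levels among them have no sign and could not be. The main log2 ratios and list medians kept their sign in every alternative with a value. The cause was not tested where none is given. Nr4a2 kept its direction in all 9 alternatives of the microglia (2.04 to 2.95), macrophage (1.88 to 2.67) and T cell (-1.86 to -0.96) comparisons, and cholesterol efflux in the macrophage comparison did so in 12 (-0.60 to -0.42). Shares below are percent of the library's cells, Nr4a2 levels CPM in control microglia-like or glioma monocyte/macrophage-like cells, and other values log2 ratios. With Leiden resolution 0.5, the Nr4a2 level of macrophages was 100.132, and microglia were 90.049% of control and 0.091% of glioma cells. With resolution 2, the level was 124.694, microglia 77.595% of control, and macrophages 2.317% of control and 67.526% of glioma. With each library clustered by itself, the level was 121.357, microglia 79.525% of control and 0.695% of glioma, and macrophages 2.612% of control and 58.776% of glioma. With 20% mitochondrial UMIs allowed, the level was 104.886 and glioma microglia 0.108%; with 5%, the level was 119.875, control microglia 81.747% and glioma macrophages 65.195%. With at least 1000 UMIs and 500 genes, the Nr4a2 level of microglia was 3.562, control microglia 77.245% and glioma macrophages 68.255%, and with 2000 UMIs control microglia 90.113%. With doublets kept, glioma macrophages were 65.142%, and in T cells MHC class II had 0.135, H2-Aa 0.066, H2-Ab1 0.374, Apoe 0.290, Cybb 0.594, Mrc1 0.898, the disease-associated list 0.286 and Nr4a2 -0.963. As a mean over cells, the Nr4a2 level of macrophages was 120.077; in T cells Nr4a2 had -1.862, activation 0.120 and naive genes -0.590; MHC class II had 1.885 in macrophages and MHC class I 0.495 in microglia. Median-of-ratios scaling gave T cell activation 0.818. With free RNA subtracted, the Nr4a2 level of microglia was 3.494; T cells had activation 0.883, cholesterol biosynthesis -0.102, Nr4a2 -1.705, Ifitm3 -1.025 and Iigp1 -7.035. In neutrophils it gave MHC class II -1.094, H2-Aa -10.047, H2-Ab1 -9.236, H2-Eb1 -9.087, naive T cell genes 0.557, Fdps -0.711 and Mylip 0.253. That subtraction set free RNA at 51.11% of glioma and 33.74% of control neutrophil UMIs and 24.65% and 24.41% of T cell UMIs, implausibly much: glioma barcodes outside cells held a median of 116 UMIs in the range just below them, against 2496 UMIs per glioma neutrophil and 7224 per glioma T cell. Its reversals are therefore weak evidence, and the largest negative values rest on the 0.5 UMIs added to a sum that it emptied. It left at most 3 UMIs in both sums, and so no ratio, for 1 named gene of the microglia comparison (Ttr), 15 of the T cell and 17 of the neutrophil comparison. Without cell type markers, the microglia comparison had homeostatic genes at -1.726 and immunosuppressive mediators at -0.088, and the latter also had -0.088 with at least 100 UMIs per gene, where fewer members entered. That minimum gave T cell activation 0.898 in neutrophils. Without control T cells above 10% microglial RNA, naive genes had -1.295. No value could be given for the microglia and macrophage comparisons at 5% mitochondrial UMIs (0 glioma microglia-like cells) or clustered jointly (3), nor for T cells at 5% (12 control cells), at resolutions 1 and 2 (41) or by library (0); Nr4a2 in glioma border-associated macrophage-like cells lacked one in 4 settings (1 to 47 cells). Of 68 list medians, 14 had a member at 0 UMIs; with such members at their bound 7 moved, by at most 0.429. Depth limits single genes: the 69 glioma microglia-like cells held 23 Nr4a2 and 2 Sqle UMIs.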

Other observations

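Of the tests below, those of lost or hidden microglia and of border-associated macrophages were written before their results were seen; the neutrophil comparison and the tests of RNA of other cells were chosen after.

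Neutrophil-like cells of the glioma (510 cells, 2104100 UMIs) had higher medians of the interferon and inflammatory lists than those of the control (80 cells, 710043 UMIs). Interferon gamma genes had a median log2 ratio of 3.8 (14 of 14 at least 2-fold higher), with the GTPases Gbp2 at 6.27 and Gbp5 at 6.84 (4.93 to 12.7, 1 control UMI). With free RNA subtracted this median was 4.70, but the members Cxcl9 and Iigp1 kept at most 3 UMIs in either sum in these shallow cells (median 2496 UMIs in glioma). Type I interferon genes had 1.86 (2.52 with a limit of 5% mitochondrial UMIs, 1.49 with doublets kept), with Ifit1 at 4.03, and MHC class I and cross-presentation 0.99, with Tap1 at 3.02. Inflammatory genes had 1.23 (0.66 with each library clustered by itself, 0.86 as a mean over cells), with Il1b at 2.19, immunosuppressive mediators 1.29, with Il1rn at 3.20 and Cd274 (PD-L1) at 3.10, and glycolysis and hypoxia genes 1.06, with Bnip3 at 3.88. Proliferation genes had -1.54 (-0.99 as a mean over cells), and Camp (-8.20), Ngp (-6.14) and Ltf (-5.91) were among the smallest ratios. Nr4a2 did not differ beyond counting error (0.36, -0.17 to 0.94). Homeostatic microglia genes had -5.98 (-2.41 without cell type markers, -1.92 with free RNA subtracted), and control neutrophil-like cells held a median of 14.82% microglial RNA.

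Clustered by itself, the glioma library also held 282 unnamed cells led by the mast cell proteases Mcpt1, Mcpt2 and Mcpt4, with a median of 1090 UMIs, and 916 unnamed cells led by Ccl12, Hes1, Ccl8 and Cx3cr1. T cell-like cells led by Tnfrsf4, Ctla4 and Icos (442 cells) were separate from those led by Ccl1, Ifng and Gzmf (273 cells) and by Gzmb and Cd8a (294 cells).

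Few glioma cells were microglia-like (69, 0.695%, clustered by library). Removed barcodes with at least 4 of 12 microglia markers equalled 0.82% of called glioma cells, where loss at the filters needed 5%; these were 81 barcodes, more than the 69 cells kept. Among 9363 other glioma cells of at least 2000 UMIs, 0.032% met the marker criterion at 2000 UMIs. Of the glioma microglia-like cells of that depth, which the same markers named, only 54.5% (41.8 to 66.9%) met it. These values argue against many cells with such markers in other classes. Microglia that had lost the markers could not be found this way, so the test cannot decide on them. Breakage between the sort and the droplets is argued against by marker RNA that was no higher in free RNA than in cells (ratio 0.85 in glioma, 0.86 in control). RNA of microglia broken earlier may have been left behind at the magnetic sort, so the test cannot decide on those. Replacement of microglia by infiltrating cells may account for the few microglia-like cells. A difference in sorting or dissection between the libraries remains open, as both are confounded with the group.

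The altered profile of the 69 cells may reflect tumour microglia or RNA of other cells in the same droplets. In the test of such RNA each glioma cluster entered as its summed profile, so RNA of cells unlike their cluster was not covered. Taken singly, 66 genes abundant in monocyte/macrophage-like cells allowed a median of 16.4% macrophage RNA (quartiles 6.8 and 31.1%). Over all mixes of the 11 glioma clusters nearest to macrophages, the upper limits of their genes allowed at most 10.8% macrophage RNA in these cells. The lower homeostatic genes needed 83.4%. At most, such RNA could bring a median of 48.9% of the excess of 6 MHC class II genes (33.0 to 64.2%), and RNA of any of the 24 other glioma clusters 55.6%, which argues against it as the whole cause but leaves a part open. For Nr4a2 the most was 11.4 CPM from macrophages and 14.0 CPM from all clusters, against an excess of 20.5 CPM with a lower limit of 10.8 CPM, so with 23 UMIs microglial expression and RNA of other cells cannot be told apart. Border-associated macrophages taken for microglia are argued against by their markers, which had a median log2 ratio of -6.06 against control border-associated macrophage-like cells.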
